A study of Mus musculus with 16 samples.

How the data were processed

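RNA was sequenced from starch-elicited peritoneal macrophages of mice in 16 samples, 4 in each of the groups L_C, L_O, H_C and H_O. Total RNA was extracted with Trizol and libraries followed standard Illumina protocols, per the labels' protocols. The authors deposited a single table of read counts per gene for the 16 samples, with 15871 entries, each with a read in at least 4 samples and of which 1594 are unannotated regions. The values are whole numbers with different totals per sample, and so were treated as counts without normalization. HISAT2, DESeq2 and the mouse genome build mm10 are named without versions, per the submitters' processing notes, and the role of each tool, the counting tool, the gene annotation and the strand setting were not given in the sources used here. Library totals lay between 32596640 and 41712885, which sets the counting error, and groups were taken from the labels. Genes of the fixed lists with no entry in the table, Il6, Il23a, Cidec, Pklr, Oga, Car12 and Ifi30 among them, were not analysed here, which left 474 of 515.

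Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided), with TMM normalization, the filterByExpr filter by group and a model with a mean for each group. All 16 samples shared an estimate of the spread with 12 residual degrees of freedom, 13527 entries passed the filter, of which 999 were unannotated regions, and 2344 were not tested. Contrasts were L_O against L_C, H_O against H_C, H_C against L_C, H_O against L_O, and the difference between the first pair of them. P-values were adjusted by the Benjamini-Hochberg method over all tested entries of a contrast, with a threshold of 0.05. Levels are the CPM of edgeR, counts scaled to library totals with TMM factors, and log2 CPM used a prior count of 2. Fold changes are on the log2 scale with their standard errors from the fit.

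The groups, the tests, the alternatives, the gene lists and the rule for the genes named in the text were fixed before the data were examined, apart from those marked otherwise below. The 28 lists cover cholesterol synthesis, LXR targets, scavenger receptors, lipid droplet and PPAR targets, NRF2 targets, inflammatory genes, interferon-stimulated genes, alternative activation, glycolysis, glucose sensing, oxidative phosphorylation, lysosome, the unfolded protein and amino acid responses, cell cycle, osmotic stress, hypoxia, MHC class II and matrix remodelling. They also hold markers of large peritoneal macrophages, small peritoneal macrophages and monocytes, B cells, T and NK cells, neutrophils, mast cells and basophils, eosinophils, mesothelial cells and fibroblasts, dendritic cells, and erythroid cells and platelets. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 28 lists of a contrast, and again with the correlation estimated from the data. The 11 lists that kept the call with an estimated correlation, out of 44 calls over the 5 contrasts, were NRF2, cholesterol synthesis and both macrophage marker lists in both ox-LDL comparisons and cell cycle, lysosome and eosinophil in the comparison in high glucose. The eosinophil list held 1 measured member, so its call is that of a single gene. It has no correlation between genes to estimate, and the gap between its values under both settings does not come from correlation. The rule named, for each pairwise contrast, the 8 largest rises and 8 largest falls among genes past the threshold with an average log2 CPM of at least 3 and no overlap between the libraries of the groups compared, a separation that a single gene reaches by chance with an exact two-sided p of 0.0286. For the interaction it named up to 6 in each direction, and from each list up to 4 members with the smallest adjusted p. Symbols without an informative name (predicted genes, Riken clones and pseudogenes) were passed over. Genes to be named in every contrast included Cd36, Msr1, Olr1, Abca1, Abcg1, Plin2, Txnip, Il1b, Tnf and Hmox1, and the text prints a subset of the genes that the rule gave.

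The alternatives were RLE and upper-quartile size factors, no low-count filter and a filter of at least 1 CPM in at least 4 samples, DESeq2 1.42.0, limma-voom, the replicate number as a block, fits of the 8 libraries compared, leaving out each library in turn, and fry and an estimated correlation for lists. Fry tests a list by itself, while camera sets it against the other genes. No scaling beyond library totals, limma-voom with array quality weights, the other scalings of the list tests, and leave-outs for the agreement between contrasts were chosen after seeing the data. With no scaling the median log2 fold change of all genes was 0.0858 for ox-LDL in low glucose and 0.0738 in high glucose, against 0.000925 and 0.00894 with TMM. The pipeline was tested on simulated counts with the real means, library sizes and spread. Genes were drawn independently, with no outlying library and no correlation between genes, so the test does not cover these features of the data. The changed genes were drawn from those with an average log2 CPM above 1. The list of interferon-stimulated genes was also shifted down, which adds to the calls. For high glucose without ox-LDL, on 13451 genes, it recovered 76.1, 94 and 100% of genes changed 1.5-, 2- and 4-fold, with 13 false calls among 202. For the interaction, on 13449 genes, it recovered 47.7, 85.1 and 97%, with 7 false calls among 169. Replicates were compared by chi-square over genes, and principal components were taken over 8672 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

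Positions and the share of each gene's 50-base stretches found in transcripts of other genes came from the GENCODE vM21 annotation of mm10, which had a transcript for 12518 (92.5%) of the tested entries. It may not be the annotation behind the counts, and named genes that share at least 5% of these stretches, or exons on the same strand, are reported as uncertain. The share applies to Aars, Apoc2, Chil3, Clec10a, Csf3r, Eno1, Gbp4, Gbp8, Glcci1, Ifit1, Ifit3, Itgax, Pkm, Rrm2, S100a4, Spp1, Tgtp1 and Tgtp2. The overlap on the same strand applies further to Slc5a3 (with Mrps6), Gclm (with Gm6061), Hsp90b1 (with Gm15344), Cd74, Scd2 and Top2a. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart, which leaves uncertain Stab1 (with Nt5dc2), Il18bp (with Numa1), Cxcl16 (with Zmynd15), Cyp51 (with Akap9), Ddit3 (with Mars), Prg4 (with Tpr), Ciita (with Dexi), H2-DMa (with Brd2), Rnaseh2c (with Kat5), Ccnd1 (with LTO1) and Gas6 (with Tmem255b). Adam8, Arhgap22, F5, Fbxo32, Gbp2, Hsp90b1, Il1b, Mgll, Oasl1, Slc6a6 and Txnip likewise overlap non-coding transcripts on the other strand.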

Results

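Macrophages washed from the peritoneal cavity of 8-week-old C57BL/6 mice after an injection of 6% starch, which draws these cells into the cavity, were profiled by RNA sequencing. The 16 libraries fell into 4 groups of 4, from low glucose medium (L_C), low glucose medium with oxidised low-density lipoprotein (L_O), medium with 33 mmol/L glucose (H_C) and medium with both additions (H_O). Oxidised low-density lipoprotein (ox-LDL) is a modified lipoprotein that macrophages take up through scavenger receptors, and the resulting foam cells are typical of atherosclerotic plaques. Treatment lasted 48 h, the ox-LDL dose is written as 50 mg/ml in the labels, a unit that is in doubt, and the L_C medium held 27.5 mM mannitol as an osmotic control, which the L_O label does not name. The purpose stated in the title is to find targets for atherosclerosis under high glucose. The labels do not say that the replicates came from separate animals or cultures, so all p-values measure only the spread between these samples, which may be technical.

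Library totals lay between 32596640 and 41712885 counts, and 13527 genes and unannotated regions were tested. On principal component 1, with 47.7% of the variance over 8672 genes, the 8 libraries with ox-LDL lay between 12.1 and 16.4 and the 8 without it between -22.7 and -10.1. On principal component 2, with 16.6%, the low glucose libraries lay between 0.456 and 21.1 and the high glucose libraries between -12.4 and -2.77. Chi-square values per degree of freedom between replicates ran from 6.48 to 97.5, so no pair differed by so little that it could be a single library deposited again. The highest of these, from 93.9 to 97.5, all involved L_C replicate 4, in which mitochondrial genes took 3.72% of the counts against 1.48 to 1.95% in the other L_C libraries and ribosomal protein genes took 1.39% against 1.77 to 1.81%.

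**Figure D1:**
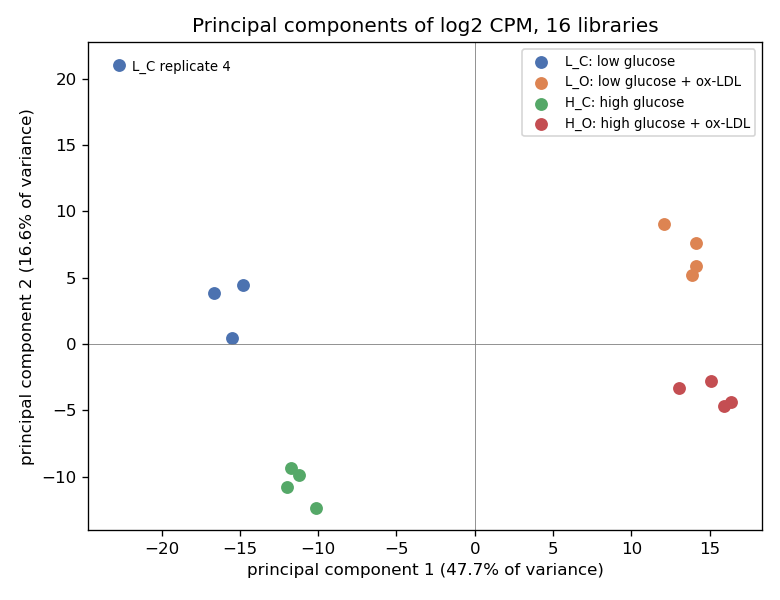
Each point is 1 of the 16 libraries, placed by its scores on the principal components with 47.7% (horizontal axis) and 16.6% (vertical axis) of the variance of log2 CPM, and colours mark the 4 groups. Libraries with and without ox-LDL lay on opposite sides of 0 on the horizontal axis, low and high glucose libraries on opposite sides of 0 on the vertical axis, and L_C replicate 4 lay at -22.7 and 21.1.

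The comparison of L_O with L_C asked what ox-LDL changed in low glucose. L_C held 27.5 mM mannitol, which the L_O label does not name, so a lack of mannitol cannot be told apart from ox-LDL here. Of 15 targets of NFAT5, the regulator of the response to osmotic stress, 6 rose and 3 fell (6 and 4 adjusted over the list alone). Their median log2 fold change was 0.185, and the list did not pass camera (adjusted p = 0.7), which does not settle the question for other genes. Angptl4, a secreted inhibitor of lipoprotein lipase on chromosome 17, 33773750 to 33781830 (mm10), rose, by 13.8-fold in the fit, from 1.85 ± 0.611 to 25.6 ± 3.41 CPM (counts scaled to library totals; mean ± SD, n = 4 per group; edgeR adjusted p = 4e-10). Clec4n, which encodes the lectin receptor Dectin-2, rose from 8.67 ± 0.983 to 52.2 ± 0.967 CPM (adjusted p = 3.51e-13), and the scavenger receptor gene Stab1 rose from 71.4 ± 3.76 to 228 ± 16.4 CPM (adjusted p = 7.53e-13). The non-classical MHC class I gene H2-M2 fell from 21.5 ± 9.03 to 2.24 ± 0.727 CPM (adjusted p = 4.03e-07), and Acod1, whose enzyme makes itaconate in activated macrophages, fell from 203 ± 44.1 to 23.3 ± 8 CPM (adjusted p = 4.81e-06). In all, 1623 of 13527 genes rose and 1867 fell at a Benjamini-Hochberg adjusted p of 0.05 in the two-sided edgeR quasi-likelihood test, 137 and 375 of them by at least 2-fold.

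Other large rises, given as log2 fold change ± SE with n = 4 per group, were in Hal (2.53 ± 0.092), Dusp6 (2.21 ± 0.15), Gas6 (2.11 ± 0.053), Ednrb (2.08 ± 0.090) and Tgfbi (1.75 ± 0.15). Hal breaks down histidine, Dusp6 is a phosphatase of ERK kinases, Gas6 is the ligand of the receptors Axl and Mertk that bind dying cells, Ednrb is an endothelin receptor, and Tgfbi is a matrix protein. Other large falls were in Ifit2 (-2.86 ± 0.64), Gbp2 (-2.51 ± 0.26), Clic5 (-2.46 ± 0.14), Mamdc2 (-2.36 ± 0.12), Gbp4 (-2.36 ± 0.45) and Tgtp1 (-2.33 ± 0.34), of which Ifit2, both Gbp genes and Tgtp1 are induced by interferons. Ifit2 stood at -3.73 in limma-voom and Gbp4 at -3.17 without L_O replicate 1. Tgtp1 shares 91.4% of its 50-base stretches with other transcripts, so its value is uncertain. The fixed list of interferon-stimulated genes held 26 measured members, of which 19 fell over all genes and 21 fell adjusted over the list alone. These included Rsad2 (-2.03 ± 0.11), Ifit1 (-1.85 ± 0.16) and Oas3 (-1.57 ± 0.077). Camera gave the list an adjusted p of 8.58e-12, and adjusted p = 0.0552 with an estimated correlation. Of 13 genes of antigen presentation by MHC class II, 9 fell and 1 rose (9 and 1 adjusted over the list alone), with H2-Aa (-2.21 ± 0.22) and Cd74 (-1.82 ± 0.16) among those that fell. Camera gave MHC class II genes an adjusted p of 4.7e-05, and adjusted p = 0.234 with an estimated correlation. Among cells that carry MHC class II, marker medians (log2 fold change) were -1.2 for dendritic cells and -1.04 for small macrophages and monocytes. For 6 B cell markers, of which 1 fell, the median was 0.0737, and for MHC class II itself it was -1.18. A change in the share of these cells was not tested here. Of 23 inflammatory genes 10 fell, such as Ccl5 (-1.62 ± 0.14), and 1 rose (11 and 2 adjusted over the list alone). Camera gave inflammatory genes an adjusted p of 0.00766, and adjusted p = 0.234 with an estimated correlation. Tnf (0.18 ± 0.14, adjusted p = 0.38) and Il1b (-2.27 ± 1.27, adjusted p = 0.213) did not pass, and Il1b was near the floor at 0.278 ± 0.206 CPM in L_C.

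Genes of sterol and redox metabolism moved as groups in low glucose. The cholesterol synthesis list, whose genes are driven by SREBP2, had 20 of 24 members lower, over all genes and adjusted over the list alone. Camera gave cholesterol synthesis an adjusted p of 2.52e-13, and adjusted p = 0.0118 with an estimated correlation. Members that fell included Insig1 (-0.67 ± 0.048), which encodes a sterol-sensing anchor protein. The NRF2 oxidative stress list had 20 of 22 members higher and 1 lower, with the same counts adjusted over the list alone, and Gclm (1.76 ± 0.050), Slc7a11 (1.5 ± 0.068), Srxn1 (1.2 ± 0.058) and Hmox1 (0.95 ± 0.060) were examples. Camera gave NRF2 genes an adjusted p of 4.55e-17, and adjusted p = 1.44e-05 with an estimated correlation. Gclm and Slc7a11 serve glutathione synthesis, Srxn1 repairs peroxiredoxins, and Hmox1 degrades haem. Scavenger receptors went both ways: 6 of 14 rose and 3 fell (6 and 6 adjusted over the list alone), with Stab1 (1.68 ± 0.057), Cd36 (1.38 ± 0.058) and Msr1 (0.47 ± 0.059) higher, Cxcl16 (-1.09 ± 0.12) lower and Olr1 (-0.57 ± 0.32) not past the threshold, and the list did not pass camera (adjusted p = 0.183). The lipid droplet and PPAR list was likewise mixed, with 6 of 18 higher and 6 lower (6 and 7 adjusted over the list alone, camera adjusted p = 0.741). The droplet coat gene Plin2 (0.91 ± 0.066) and Cpt1a (1.33 ± 0.046), which admits fatty acids to mitochondria, rose, while Fabp4 (-0.66 ± 0.045) fell. Of 15 LXR targets, 3 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.237): Abcg1 (-0.44 ± 0.040) and Scd2 (-1.18 ± 0.11) fell, Mylip (0.60 ± 0.054) rose, and Abca1 (-0.03 ± 0.064) did not pass.

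Among the remaining lists in low glucose, 11 of 24 genes of the unfolded protein and amino acid responses rose and 3 fell, with the same counts adjusted over the list alone, and Asns (0.99 ± 0.094) was an example. Camera gave the unfolded protein and amino acid responses an adjusted p of 0.014, and adjusted p = 0.234 with an estimated correlation. Without L_C replicate 4 that list had an adjusted p of 0.0544. The cell cycle list had 8 of 34 members higher and 1 lower, the same adjusted over the list alone. An example was Mcm2 (0.69 ± 0.083). Camera gave the cell cycle list an adjusted p of 0.00766, and adjusted p = 0.203 with an estimated correlation. Lysosome genes fell more often than they rose, 15 against 4 of 30 (16 and 5 adjusted over the list alone), with Ctss (-0.56 ± 0.058) among those that fell. Camera gave lysosome genes an adjusted p of 0.00547, and adjusted p = 0.0552 with an estimated correlation. In oxidative phosphorylation 6 of 31 rose (5 adjusted over the list alone), with a median log2 fold change of 0.15, and of 0.08 without L_C replicate 4. Camera gave oxidative phosphorylation an adjusted p of 0.00117, and adjusted p = 0.485 with an estimated correlation. The arrestin gene Txnip fell by 0.24 ± 0.050, or by 0.16 with no scaling beyond library totals. Marker genes of cell subsets moved with ox-LDL as well. Of 14 markers of large peritoneal macrophages 6 fell over all genes and over the list alone, including F10 (-1.16 ± 0.052) and Prg4 (-1.21 ± 0.23), of which Prg4 stood at -0.78 without L_C replicate 4. Camera gave large macrophage markers an adjusted p of 0.00164, and adjusted p = 0.0191 with an estimated correlation. Of 9 markers of small peritoneal macrophages and monocytes 6 fell (7 adjusted over the list alone). These included Clec12a (-1.17 ± 0.063) and Itgax (-1.01 ± 0.056). Camera gave small macrophage and monocyte markers an adjusted p of 2.33e-05, and adjusted p = 0.0119 with an estimated correlation. The only measured eosinophil marker, Siglecf, fell by 2.07 ± 0.13 on the log2 scale. Camera gave the eosinophil marker an adjusted p of 0.0119, and adjusted p = 0.0609 with an estimated correlation. As for T and NK cells, 3 of 10 markers fell (4 adjusted over the list alone). Camera gave T and NK cell markers an adjusted p of 0.0404, and adjusted p = 0.234 with an estimated correlation. That last list ended above the threshold without L_C replicate 2, L_C replicate 4, L_O replicate 2 or L_O replicate 4 (adjusted p = 0.0838, 0.0605, 0.0652 and 0.0825). With no scaling beyond library totals, a setting chosen after seeing the data, 2857 genes rose and 1392 fell.

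In high glucose, H_O was compared with H_C, which asked what ox-LDL changed in cells already in high glucose. Angptl4 rose, by 15.2-fold in the fit, from 2.3 ± 0.733 to 35.2 ± 2.69 CPM (mean ± SD, n = 4 per group; edgeR adjusted p = 2.33e-10), Clec4n rose from 8.01 ± 0.415 to 67.7 ± 6.51 CPM (adjusted p = 6.89e-14), and the collagenase gene Mmp8 rose from 4.86 ± 0.565 to 32.3 ± 8.84 CPM (adjusted p = 2.79e-07). Mamdc2 fell from 257 ± 10.1 to 39.5 ± 8.23 CPM (adjusted p = 2.24e-11), and Fbxo32, a subunit of a ubiquitin ligase, fell from 236 ± 6.47 to 67.7 ± 3.97 CPM (adjusted p = 3.52e-12). Over all genes, 1406 rose and 1556 fell, 170 and 195 of them by at least 2-fold. With no scaling beyond library totals the split was 2176 higher and 1166 lower.

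Further large rises, as log2 fold change ± SE, were in Hal (2.92 ± 0.10), Dusp6 (2.73 ± 0.15), Tgfbi (2.21 ± 0.15), Spred2 (1.83 ± 0.11) and Dusp4 (1.83 ± 0.15), of which Dusp6, Spred2 and Dusp4 encode negative regulators of ERK signalling. Large falls were in H2-M2 (-2.27 ± 0.31), Siglecf (-2.07 ± 0.13), Ifit2 (-2.01 ± 0.64), Htra1 (-1.82 ± 0.11), Sdc1 (-1.81 ± 0.11) and Gadd45b (-1.74 ± 0.10). The adjusted p of Ifit2 was 0.0296 (0.00466 to 0.0623 over the alternatives), and it lay between 0.0546 and 0.0623 in DESeq2 and without H_C replicate 2, 3 or 4 or H_O replicate 1 or 3. The log2 fold change of Ifit2 ran from -3.15 to -1.61 over the same alternatives. The NRF2 list had 19 of 22 members higher, the same adjusted over the list alone. Examples were Gclm (1.73 ± 0.050), Slc7a11 (1.61 ± 0.068) and Hmox1 (1.03 ± 0.060). Camera gave NRF2 genes an adjusted p of 7.3e-18, and adjusted p = 1.12e-05 with an estimated correlation. In cholesterol synthesis 16 of 24 members fell, and 18 adjusted over the list alone, with Insig1 (-0.66 ± 0.048) among them. Camera gave cholesterol synthesis an adjusted p of 4.57e-13, and adjusted p = 0.0126 with an estimated correlation. Scavenger receptors were again mixed, with 6 of 14 higher and 3 lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.0885): Stab1 (1.5 ± 0.056), Cd36 (1.47 ± 0.058) and Msr1 (0.84 ± 0.059) rose, and Olr1 (-0.85 ± 0.33) did not pass (adjusted p = 0.0795, and 0.0454 to 0.211 over the alternatives, lowest without L_C replicate 1). Of 18 lipid droplet and PPAR genes 7 rose and 7 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.624), with Cpt1a (1.45 ± 0.046) and Plin2 (0.81 ± 0.066) higher and Mgll (-0.95 ± 0.052), a monoacylglycerol lipase gene, lower. Of 15 LXR targets 5 rose and 7 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.887). Abca1 (0.44 ± 0.064) rose, and Abcg1 (-0.16 ± 0.039) fell with an adjusted p of 0.0051 (0.000248 to 0.101 over the alternatives, highest with no scaling beyond library totals). Txnip fell by 0.15 ± 0.050 (adjusted p = 0.0458), a call that did not hold under 15 of the alternatives, among them most of those that left out an H_C or H_O library (0.00491 to 0.331).

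The cell cycle list had 16 of 34 members higher in high glucose with ox-LDL than without, and 20 adjusted over the list alone, including Rrm2 (1.44 ± 0.19) and Mcm2 (0.80 ± 0.083), which serve DNA replication. Camera gave the cell cycle list an adjusted p of 2.8e-08, and adjusted p = 0.0126 with an estimated correlation. In the unfolded protein and amino acid response list 13 of 24 rose and 2 fell (15 and 2 adjusted over the list alone). An example was Asns (1.11 ± 0.10). Camera gave the unfolded protein and amino acid responses an adjusted p of 5.2e-05, and adjusted p = 0.0647 with an estimated correlation. Of 26 interferon-stimulated genes 14 fell, 15 adjusted over the list alone. Examples were Oas3 (-1.52 ± 0.077) and Rsad2 (-1.35 ± 0.11). Camera gave interferon-stimulated genes an adjusted p of 4.94e-07, and adjusted p = 0.133 with an estimated correlation. MHC class II genes did not pass as a list (camera adjusted p = 0.226), with 4 of 13 lower and 1 higher (5 and 1 adjusted over the list alone), although Cd74 (-0.87 ± 0.16) fell, and without H_O replicate 2 the list's adjusted p was 0.00998. Inflammatory genes split evenly, 5 higher and 5 lower of 23 (5 and 6 adjusted over the list alone, camera adjusted p = 0.436): Ccl2 (1.69 ± 0.29) and Tnf (0.80 ± 0.14) rose, Ccl5 (-1.48 ± 0.13) fell, and Il1b (0.16 ± 1.24) did not pass. Lysosome genes fell in 17 of 30 cases and rose in 2 (17 and 3 adjusted over the list alone). Lower members included Ctss (-0.44 ± 0.058). Camera gave lysosome genes an adjusted p of 0.000371, and adjusted p = 0.0213 with an estimated correlation. Glycolysis had 6 of 20 members higher and 2 lower (6 and 3 adjusted over the list alone), with Pkm (0.58 ± 0.043) and Eno1 (0.61 ± 0.046) higher, which share 34.4 and 72.2% of their 50-base stretches with other transcripts. Camera gave glycolysis an adjusted p of 0.0483, and adjusted p = 0.547 with an estimated correlation. Oxidative phosphorylation had 5 of 31 higher (4 adjusted over the list alone). Camera gave oxidative phosphorylation an adjusted p of 0.00586, and adjusted p = 0.73 with an estimated correlation. This call ended with fry (adjusted p = 0.0806), and without L_C replicate 4 the number higher was 16 of 31. The glycolysis call ended at an adjusted p of 0.0569 with RLE size factors, and at 0.0501 to 0.101 without L_C replicate 1, L_O replicate 3, H_C replicate 2, 3 or 4, or H_O replicate 2 or 3. Markers of large peritoneal macrophages fell in 6 and rose in 1 of 14 cases, the same adjusted over the list alone. Lower members included F10 (-1.14 ± 0.052). Camera gave large macrophage markers an adjusted p of 0.00968, and adjusted p = 0.0422 with an estimated correlation. The markers of small macrophages and monocytes fell in 4 of 9, the same adjusted over the list alone. Lower members included Itgax (-1.04 ± 0.056) and Clec12a (-0.99 ± 0.063). Camera gave small macrophage and monocyte markers an adjusted p of 0.000541, and adjusted p = 0.0278 with an estimated correlation. Siglecf is also the only measured member of the eosinophil list. Camera gave the eosinophil marker an adjusted p of 0.00801, and adjusted p = 0.0431 with an estimated correlation.

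Fold changes of ox-LDL at both glucose levels were set side by side, from libraries that the comparisons do not share. Across the 13527 genes, which are not independent replicates, Pearson's r was 0.495 and Spearman's rho 0.594. In both comparisons 961 genes rose, against 169 expected from independent lists, 1207 fell, against 215 expected, and 5 moved in opposite directions, against 381 expected. Mrc1, the mannose receptor gene and a marker of alternative activation, was one of those that rose in both, by 1.13 ± 0.047 and 1.09 ± 0.047 (log2 fold change ± SE, n = 4 per group). With a stricter low-count filter r was 0.695.

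**Figure D2:**
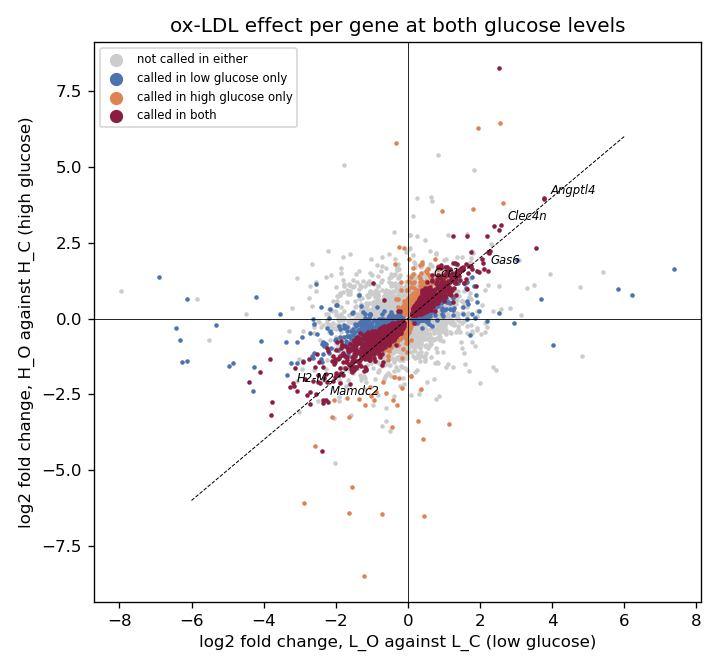
Each point is a gene, with its log2 fold change of ox-LDL in low glucose on the horizontal axis and in high glucose on the vertical axis, and colours mark where its adjusted p was under 0.05. Of the genes past the threshold at both glucose levels, 961 lie in the upper right, 1207 in the lower left and 5 in the other parts, and the dashed line marks equal changes.

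H_C against L_C asked what high glucose changed without ox-LDL. Slco4a1, an organic anion transporter gene on chromosome 2, 180456245 to 180474867 (mm10), rose from 0.654 ± 0.189 to 6.96 ± 1.62 CPM (mean ± SD, n = 4 per group; edgeR adjusted p = 4.57e-07). Slc6a12, the betaine transporter gene on chromosome 6, 121343076 to 121365775, rose from 1.03 ± 0.454 to 11.6 ± 2.39 CPM (adjusted p = 4.51e-07), and Slc5a3, the myo-inositol transporter gene on chromosome 16, 92058322 to 92087473, rose from 5.84 ± 1.38 to 15.5 ± 2.75 CPM (adjusted p = 1.57e-05). The interferon-induced GTPase genes fell, Gbp2 from 334 ± 74.3 to 92.9 ± 14.8 CPM (adjusted p = 0.000111) and Iigp1 from 91.4 ± 26.2 to 17.1 ± 3.61 CPM (adjusted p = 0.000664). In all, 679 genes rose and 1049 fell, 37 and 106 of them by at least 2-fold, and with no scaling beyond library totals 927 rose and 841 fell. When the fit held only these 8 libraries, 914 genes passed.

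Of 15 targets of NFAT5, the regulator of the response to osmotic stress, 5 rose and 1 fell, the same adjusted over the list alone. Camera gave NFAT5 targets an adjusted p of 0.00896, and adjusted p = 0.0693 with an estimated correlation. Besides Slc6a12 (3.48 ± 0.26) and Slc5a3 (1.41 ± 0.16), these included the transporter genes Slc38a2 (0.80 ± 0.048) and Slc6a6 (0.24 ± 0.048), which carry amino acids and taurine. Other rises were in S100a4 (1.42 ± 0.25), Prokr1 (0.86 ± 0.14), Htra1 (0.80 ± 0.10), Rnaseh2c (0.79 ± 0.21) and Arhgap22 (0.78 ± 0.077). Slc5a3 shares exons with Mrps6 and S100a4 shares 56.3% of its 50-base stretches with other transcripts, which leaves both values uncertain. Rnaseh2c, at 3.6 CPM in L_C replicate 4 and at least 9.76 in the other L_C libraries, had an adjusted p of 0.0194 (0.000467 to 0.116 over the alternatives), which was 0.116 in the fit of these 8 libraries, 0.0539 without H_C replicate 1 and 0.0541 without H_C replicate 2. Among 16 genes of glucose sensing, the polyol pathway and the hexosamine pathway 3 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.933). Txnip, a glucose-induced arrestin gene, rose (0.21 ± 0.050, adjusted p = 0.00888, with 0.00109 to 0.0533 over the alternatives, highest in the fit of these 8 libraries), and Arrdc3 (-0.86 ± 0.14) and Gfpt1 (-0.42 ± 0.064) fell.

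Falls named by size were in Gbp4 (-2.54 ± 0.46), Iigp1 (-2.42 ± 0.41), Tgtp1 (-1.88 ± 0.33), Gbp2 (-1.85 ± 0.25), Gbp8 (-1.83 ± 0.18), Il18bp (-1.79 ± 0.25), Tgtp2 (-1.76 ± 0.35) and Gbp5 (-1.60 ± 0.25), all genes that interferons induce. Gbp4 and Gbp8 overlap each other and Gbp9, and Tgtp1 and Tgtp2 share 91.4 and 90.6% of their 50-base stretches with other transcripts, so reads could be split between them. In the fixed list of interferon-stimulated genes 16 of 26 fell and 17 fell adjusted over the list alone. Examples were Ifit3 (-1.33 ± 0.16), Ifit1 (-1.17 ± 0.15) and Rsad2 (-1.17 ± 0.11). Camera gave interferon-stimulated genes an adjusted p of 3.26e-13, and adjusted p = 0.0693 with an estimated correlation. Ifit3 shares 51.2% of its 50-base stretches with other transcripts. Of 13 genes of antigen presentation by MHC class II 9 fell and 10 fell adjusted over the list alone. These included Ciita (-1.18 ± 0.23), H2-DMa (-1.01 ± 0.13) and Cd86 (-0.79 ± 0.13). Camera gave MHC class II genes an adjusted p of 2.98e-08, and adjusted p = 0.112 with an estimated correlation. Ciita is known as a regulator of MHC class II genes, and Cd86 encodes a co-stimulatory protein rather than a class II chain. Markers of small peritoneal macrophages and monocytes were also examined, with 3 lower and 1 higher of 9 (4 and 1 adjusted over the list alone). Lower members included Clec12a (-0.56 ± 0.063) and Itgax (-0.36 ± 0.055). Camera gave small macrophage and monocyte markers an adjusted p of 0.0116, and adjusted p = 0.104 with an estimated correlation. The neutrophil markers had 1 of 5 members lower, the same adjusted over the list alone. Camera gave neutrophil markers an adjusted p of 0.0433, and adjusted p = 0.112 with an estimated correlation. The neutrophil call ended without L_C replicate 1, L_C replicate 4 or H_C replicate 4 (adjusted p = 0.058, 0.0766 and 0.0903).

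Cholesterol synthesis genes also fell in high glucose, 11 of 24 over all genes and 12 adjusted over the list alone. Examples were Cyp51 (-0.50 ± 0.070) and Sqle (-0.46 ± 0.068). Camera gave cholesterol synthesis an adjusted p of 1.11e-05, and adjusted p = 0.104 with an estimated correlation. The unfolded protein and amino acid response list had 14 of 24 members lower, or 15 lower and 1 higher adjusted over the list alone, with the chaperone genes Calr (-0.36 ± 0.050) and Hsp90b1 (-0.33 ± 0.044) and the serine synthesis gene Psat1 (-0.65 ± 0.13) among them. Camera gave the unfolded protein and amino acid responses an adjusted p of 1.23e-07, and adjusted p = 0.0693 with an estimated correlation. In matrix remodelling 8 of 20 fell and 2 rose (9 and 2 adjusted over the list alone), with Plau (-1.13 ± 0.11), the urokinase gene, as an example. Camera gave matrix remodelling an adjusted p of 0.0153, and adjusted p = 0.312 with an estimated correlation. Without L_C replicate 4 the matrix list had an adjusted p of 0.121. Of 15 LXR targets 2 rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.237): Apoe (0.42 ± 0.043) rose, and Abca1 (-0.59 ± 0.064), Lpl (-0.89 ± 0.14) and Abcg1 (-0.15 ± 0.039) fell. Scavenger receptors split evenly, 4 higher and 4 lower of 14, the same adjusted over the list alone (camera adjusted p = 0.933), with Msr1 (-0.60 ± 0.059) and Cd36 (-0.21 ± 0.057) lower and Olr1 (-0.49 ± 0.32) not past the threshold. The falls of Cd36 and Abcg1, with adjusted p of 0.0224 and 0.0157, ended at 0.0748 and 0.0766 with no scaling beyond library totals and at 0.0945 and 0.114 in the fit of these 8 libraries. Leaving out L_C replicate 3, H_C replicate 2 or H_C replicate 3 gave Cd36 0.0781, 0.0551 and 0.0866, and leaving out H_C replicate 1 or 3 gave Abcg1 0.0539 and 0.0949 (over all alternatives 0.00125 to 0.0945 and 0.00251 to 0.114). Among inflammatory genes 4 of 23 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.252), and Tnf (-0.95 ± 0.14) and Nlrp3 (-0.55 ± 0.10) were lower. The pyruvate kinase gene Pkm (0.31 ± 0.043) rose and Mgll (-0.55 ± 0.051) fell, while Plin2 (0.05 ± 0.065), Hmox1 (-0.02 ± 0.060) and Il1b (-1.37 ± 1.18) did not pass (adjusted p = 0.656, 0.895 and 0.506).

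H_O against L_O asked what high glucose changed in cells that also received ox-LDL. Slco4a1 rose, by 28.2-fold in the fit, from 0.859 ± 0.322 to 24.5 ± 4.95 CPM (mean ± SD, n = 4 per group; edgeR adjusted p = 6.99e-09), and Slc6a12 rose from 1.37 ± 0.259 to 16.7 ± 4.24 CPM (adjusted p = 1.9e-07). Cd14, the co-receptor for lipopolysaccharide, rose from 44.8 ± 4.66 to 102 ± 6.7 CPM (adjusted p = 1.88e-08). Mgll fell from 142 ± 5.71 to 78.6 ± 3.19 CPM (adjusted p = 1.88e-08), and Cd5l, a secreted macrophage protein that inhibits apoptosis, fell from 69.6 ± 3.8 to 36.2 ± 4.38 CPM (adjusted p = 0.000766). In all, 367 genes rose and 459 fell, 45 and 20 of them by at least 2-fold. The total of 826 became 1763 without L_C replicate 4, a library outside this comparison that adds to the shared estimate of the spread, 1619 in a fit of these 8 libraries, 526 without L_O replicate 1 and 549 without L_O replicate 4.

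Further rises, as log2 fold change ± SE, were in Glcci1 (1.75 ± 0.43), S100a4 (1.33 ± 0.24), Htra1 (1.26 ± 0.11), Slc5a3 (1.25 ± 0.15), Slc27a6 (1.01 ± 0.17) and Marveld1 (0.95 ± 0.086), and further falls in Gbp8 (-1.05 ± 0.18), Ccnd1 (-1.04 ± 0.22), Arrdc3 (-0.93 ± 0.15), Prune2 (-0.92 ± 0.11), F5 (-0.91 ± 0.13) and Mef2c (-0.86 ± 0.14). Glcci1, which stood at 2.99 without L_O replicate 1, had an adjusted p of 0.0202 (1.06e-09 to 0.0693 over the alternatives), which was 0.068, 0.0619 and 0.0693 without L_O replicates 2, 3 and 4, and it shares 87.9% of its 50-base stretches with other transcripts. Slc27a6 encodes a fatty acid transporter, Ccnd1 a cyclin, F5 a coagulation factor and Mef2c a transcription factor. Of 15 NFAT5 targets 5 rose, or 5 rose and 1 fell adjusted over the list alone. Higher members included Slc6a12 (3.60 ± 0.26), Slc38a2 (0.60 ± 0.048) and Sgk1 (0.32 ± 0.052). Camera gave NFAT5 targets an adjusted p of 0.00134, and adjusted p = 0.0509 with an estimated correlation. Interferon-stimulated genes fell in 4 of 26 cases (9 lower and 1 higher adjusted over the list alone). Lower members included Rsad2 (-0.49 ± 0.11), Oasl1 (-0.49 ± 0.086) and Ddx58 (-0.38 ± 0.078). Camera gave interferon-stimulated genes an adjusted p of 4.84e-05, and adjusted p = 0.294 with an estimated correlation. The number of these lower over all genes was 8 without L_C replicate 4. The MHC class II list did not pass (camera adjusted p = 0.677, median log2 fold change 0.00421 over 13 members), and without H_O replicate 2 it passed as lower with an adjusted p of 0.0385. In the unfolded protein and amino acid response list 7 of 24 fell and 1 rose (9 and 1 adjusted over the list alone). Lower members included Ddit3 (-0.58 ± 0.093) and Aars (-0.23 ± 0.040). Camera gave the unfolded protein and amino acid responses an adjusted p of 9.03e-05, and adjusted p = 0.237 with an estimated correlation. Cholesterol synthesis had 6 of 24 members lower (9 lower and 1 higher adjusted over the list alone). Lower members included Sqle (-0.43 ± 0.069). Camera gave cholesterol synthesis an adjusted p of 0.00044, and adjusted p = 0.26 with an estimated correlation. Glycolysis had 3 of 20 members higher, the same adjusted over the list alone, with Pkm at 0.36 ± 0.043. Camera gave glycolysis an adjusted p of 0.0153, and adjusted p = 0.401 with an estimated correlation. The cell cycle list had 1 of 34 higher, the same adjusted over the list alone. Camera gave the cell cycle list an adjusted p of 0.0145, and adjusted p = 0.294 with an estimated correlation.

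Lipid handling genes were examined in the same comparison. Of 15 LXR targets 3 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0767): Apoc2 (1.37 ± 0.19) and Apoe (0.42 ± 0.043) rose, Lpl (-0.83 ± 0.14) fell, and Abca1 (-0.12 ± 0.064) and Abcg1 (0.12 ± 0.039) did not pass. Apoc2 shares 88.2% of its 50-base stretches with other transcripts, so its value is uncertain. Among scavenger receptors 4 of 14 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.677), with Cxcl16 (0.74 ± 0.12) higher, Msr1 (-0.24 ± 0.058) lower and Cd36 (-0.12 ± 0.057) and Olr1 (-0.77 ± 0.33) not past the threshold. The call of Msr1 ended without L_O replicate 1, H_O replicate 3 or H_O replicate 4 (adjusted p = 0.085, 0.068 and 0.0692, with 0.000437 to 0.085 over all alternatives). Abcg1, at an adjusted p of 0.0825, passed in DESeq2 (0.0394), in the fit of these 8 libraries (0.0293) and without L_C replicate 4 (0.0223), with 0.0189 to 0.228 over all alternatives. Of the inflammatory list 2 of 23 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.288), with Ccl5 (0.79 ± 0.14) higher and Il1b (1.06 ± 1.33) and Tnf (-0.32 ± 0.14) not past the threshold, although Tnf, at 0.185, had an adjusted p of 0.0379 without L_O replicate 2 (0.0379 to 0.479 over the alternatives). Txnip (0.31 ± 0.050) and Adam8 (0.41 ± 0.050), a metalloprotease gene, rose, Itgax (-0.38 ± 0.055) and Clec12a (-0.38 ± 0.063) fell, and Plin2 (-0.04 ± 0.065) and Hmox1 (0.07 ± 0.059) did not pass.

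Fold changes of high glucose without and with ox-LDL, also from libraries that the comparisons do not share, had a Pearson's r of 0.276 and a Spearman's rho of 0.411 across the 13527 genes, which are not independent replicates. In both comparisons 210 genes rose, against 18.4 expected from independent lists, 309 fell, against 35.6 expected, and 3 moved in opposite directions, against 51.5 expected. Htra1, a serine protease gene, rose in both, by 0.80 ± 0.10 and 1.26 ± 0.11 (log2 fold change ± SE, n = 4 per group). With a stricter low-count filter r was 0.434, and without H_C replicate 3 it was 0.184.

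**Figure D3:**
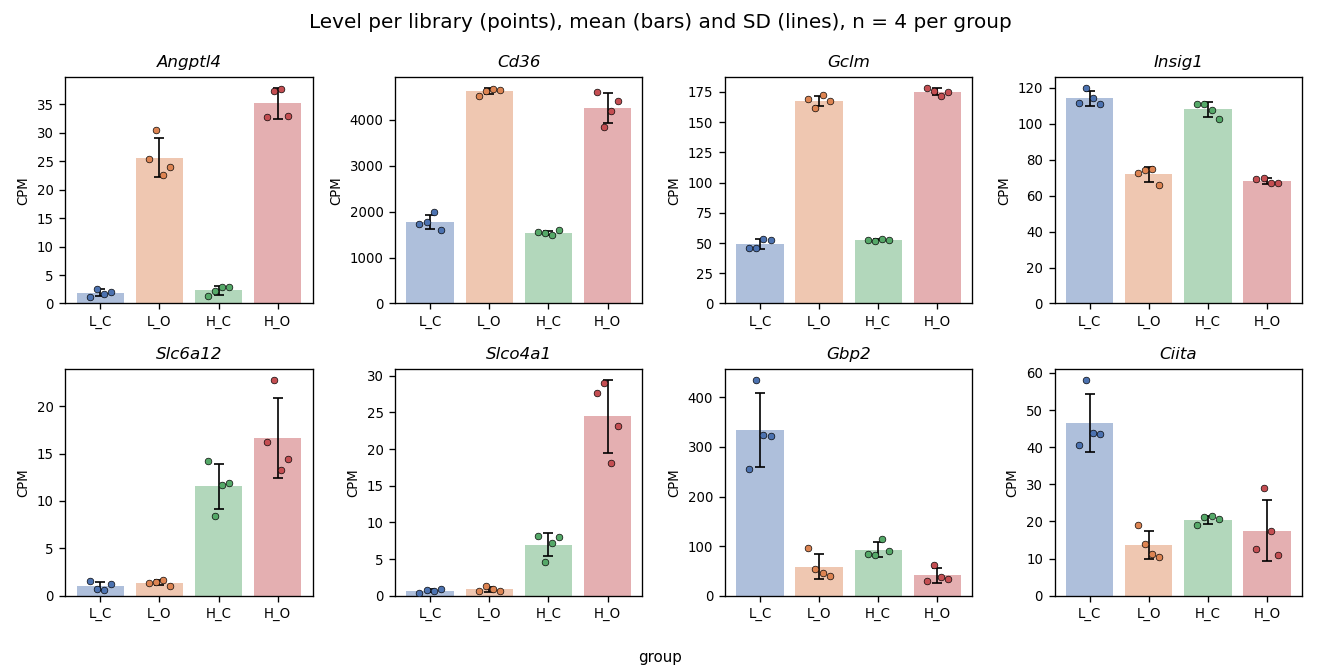
Bars show the mean and lines the SD of CPM (vertical axes) over the 4 libraries of each group, with 1 point per library. Angptl4, Cd36 and Gclm were higher in both groups with ox-LDL, Insig1 was lower there, Slc6a12 and Slco4a1 were higher in both groups with high glucose, and Gbp2 and Ciita were highest in L_C, at 334 ± 74.3 and 46.5 ± 7.8 CPM.

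The interaction asked whether ox-LDL acted differently at the glucose levels, as the effect in high glucose minus that in low glucose. The effect in low glucose includes any difference in mannitol between L_C and L_O, which cannot be told apart from ox-LDL. Ccr1, a chemokine receptor gene on chromosome 9, 123962124 to 123968692 (mm10), went from 80.7 ± 6.7 to 117 ± 11.2 CPM with ox-LDL in low glucose and from 46.3 ± 1.57 to 106 ± 7.5 CPM in high glucose (mean ± SD, n = 4 per group), an interaction of 0.65 ± 0.10 on the log2 scale (edgeR adjusted p = 0.0381). Gas6, on chromosome 8, 13465374 to 13494490, went from 63.5 ± 4.64 to 274 ± 13 CPM in low glucose and from 109 ± 2.85 to 340 ± 12 CPM in high glucose, an interaction of -0.46 ± 0.072 (adjusted p = 0.0381). Gas6 overlaps exons of Tmem255b on the other strand, and the strand setting of the counting was not given in the sources used here. These 2 genes were the only ones of 13527 past the threshold in this test, against 1161 at an unadjusted p under 0.05, 95 in DESeq2 and 0 in limma-voom. Without L_C replicate 4 the count was 53, without L_C replicate 1 it was 21, without L_O replicate 1 it was 19, without H_C replicate 3 it was 3, and without each of the other 12 libraries it was 0. Both genes lost the call in limma-voom (adjusted p = 0.0553) and in 12 of the 16 fits that left out a library, with adjusted p of 6.37e-06 to 0.146 for Ccr1 and 4.35e-06 to 0.146 for Gas6 over all alternatives.

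As lists, 6 passed camera, all with a higher log2 effect of ox-LDL in high glucose than in low glucose, and none of them kept the call with an estimated correlation. The MHC class II list had a median interaction of 0.88 over 13 members, of which 8 passed adjusted over the list alone, and its members included Ciita (1.54 ± 0.33), Cd74 (0.95 ± 0.22) and H2-DMa (0.81 ± 0.19). Camera gave MHC class II genes an adjusted p of 9.74e-10, and adjusted p = 0.139 with an estimated correlation. Markers of small macrophages and monocytes had a median of 0.44 over 9 members and did not pass (camera adjusted p = 0.0626). Their adjusted p was 0.0384 with the replicate number as a block, 0.049, 0.0208, 0.0159 and 0.0437 without L_C replicate 4, L_O replicate 2, H_O replicate 1 and H_O replicate 4, and 0.112 with fry. Interferon-stimulated genes had a median of 0.44 over 26 members, with 7 past the threshold adjusted over the list alone, such as Ifit1 (1.12 ± 0.22) and Rsad2 (0.68 ± 0.15). Camera gave interferon-stimulated genes an adjusted p of 2.53e-07, and adjusted p = 0.208 with an estimated correlation. Matrix remodelling had a median of 0.58 over 20 members, with 10 higher and 1 lower adjusted over the list alone. Examples were Mmp8 (1.49 ± 0.35) and Spp1 (0.66 ± 0.13). Camera gave matrix remodelling an adjusted p of 6.71e-06, and adjusted p = 0.139 with an estimated correlation. Mesothelial and fibroblast markers, which include matrix genes, went the same way, with a median of 0.74 over 13 members (camera adjusted p = 0.0785, or 1.63e-05 without H_C replicate 3 and 0.021 without H_O replicate 3). LXR targets had a median of 0.14 over 15 members, with 4 past the threshold adjusted over the list alone. Examples were Abca1 (0.47 ± 0.090) and Abcg1 (0.27 ± 0.056). Camera gave LXR targets an adjusted p of 4.04e-05, and adjusted p = 0.066 with an estimated correlation. The cell cycle list had a median of 0.21 over 34 members. An example was Top2a (0.72 ± 0.19). Camera gave the cell cycle list an adjusted p of 6.71e-06, and adjusted p = 0.0676 with an estimated correlation. The inflammatory list had one of 0.29 over 23, with 5 past the threshold adjusted over the list alone and Tnf (0.63 ± 0.19) as an example. Camera gave inflammatory genes an adjusted p of 0.00434, and adjusted p = 0.308 with an estimated correlation. The inflammatory call ended without H_O replicate 2 (adjusted p = 0.0544) and with fry (0.13), and the interferon call with fry (0.0639). Without L_C replicate 4 the lists past the threshold were 11, with glycolysis (0.000125) and the unfolded protein and amino acid responses (0.00316) among those added. Over all genes none of these members passed in edgeR, where Ifit1, Abca1 and Spp1 came nearest of those named, at an adjusted p of 0.0774 each. In the fit without L_C replicate 4, 3 interferon-stimulated genes and 2 each of the MHC class II, LXR and matrix lists passed. In DESeq2 each of the members named here except Cd74 and Tnf passed, as did Msr1, with adjusted p of 0.000335 to 0.0469. Of genes fixed beforehand, Cd36 (0.09 ± 0.080), Msr1 (0.37 ± 0.083), Olr1 (-0.28 ± 0.46), Plin2 (-0.10 ± 0.092), Txnip (0.10 ± 0.071), Hmox1 (0.09 ± 0.084) and Il1b (2.43 ± 1.78) did not pass either.

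**Figure D4:**
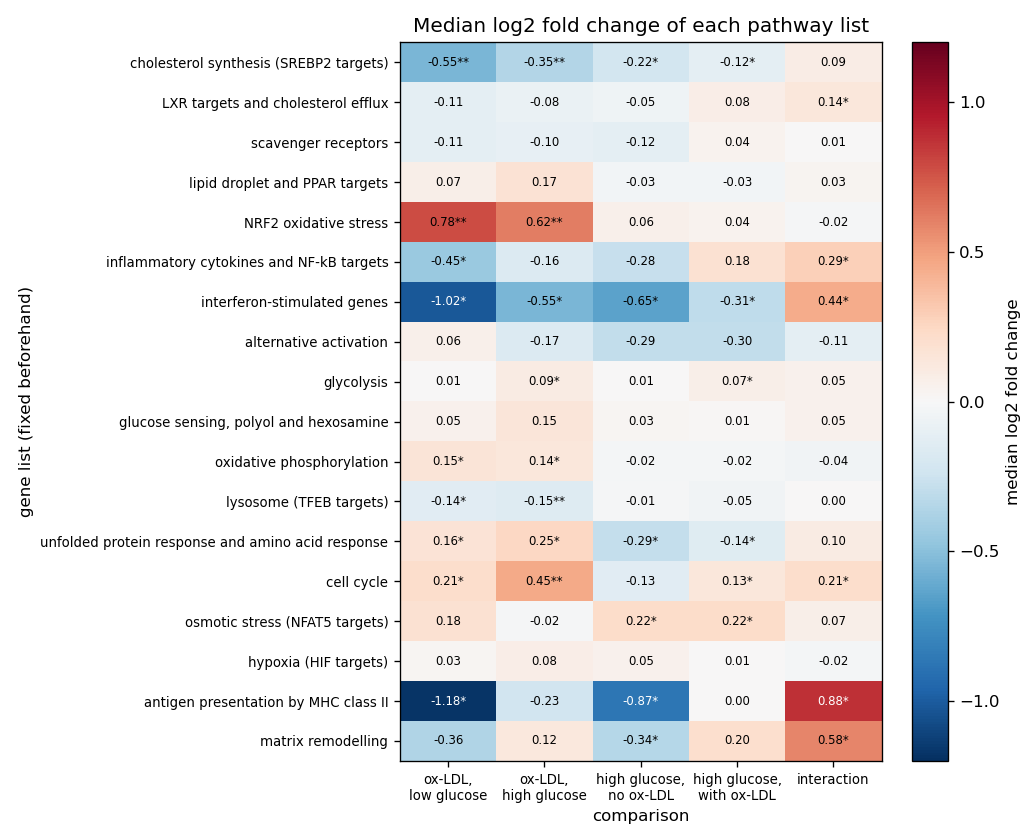
Each cell gives the median log2 fold change of a pathway list (rows of the plot) in a comparison (columns of the plot), where 1 asterisk marks a camera adjusted p under 0.05 with the preset correlation and a pair of asterisks marks lists that also passed with an estimated correlation. The lowest medians were -1.18 for MHC class II and -1.02 for interferon-stimulated genes with ox-LDL in low glucose, and NRF2 genes reached 0.78.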

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

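The test for cells of another type in L_C replicate 4, whose bound was rewritten more than once after its value was seen, and both tests on the interferon and MHC class II lists were chosen only after the result was seen. A library stood apart where its gap to the nearest other library of its group, as a fraction of the group's range, was above the 95% limit for 4 values. This held in 44 of 588 groups, and chance alone gives about 1 in 20 groups (5 percent). L_C replicate 4 was the outlying library in 8 of them.

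L_C replicate 4 had the lowest mean correlation with its group, 0.974 against 0.987 (gap of 0.985 of the range), the lowest share of ribosomal protein counts, 1.39% (0.889), and the lowest score of oxidative phosphorylation genes, -0.372 (0.95). Its 13 mitochondrial genes had a median log2 deviation of 1.33 from the other L_C libraries, 86 ribosomal protein genes one of -0.34, Gapdh one of 1.77, and 123 genes were off by at least 2-fold, against at most 27 in any other library. Transcript length explained 3.7% and GC content 1.23% of the variance of its deviation across genes, which argues against both as the cause. The highest median deviation of a marker list of another cell type was 0.498, for neutrophils, of which Csf3r stood at 180 CPM against 128. It was 0.42 for T and NK cells, 0.33 for B cells, 0.157 for mesothelial cells and fibroblasts, 0.0881 for erythroid cells and platelets and -0.607 for dendritic cells. The highest T and NK cell and B cell markers reached only 3.17 and 2.86 CPM in this library. Such medians went up to 1.78 in other libraries, so cells of another type cannot be told apart from the other explanations. RNA quality, handling or a different culture may also account for the pattern, and no biological explanation was tested because the labels name no difference between the replicates.

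The lists of MHC class II and interferon-stimulated genes were lower with high glucose without ox-LDL (camera adjusted p = 2.98e-08 and 3.26e-13, and adjusted p = 0.112 and 0.0693 with an estimated correlation) and differed in the interaction (9.74e-10 and 2.53e-07, and adjusted p = 0.139 and 0.208 with an estimated correlation), so each camera call rests on the preset correlation. Without L_C replicate 4 the interferon list had an adjusted p of 1.02e-06 in the interaction, which argues against that library alone as the cause, and without H_O replicate 2, which was high in several such genes, it had one of 6.6e-06, but with fry it had one of 0.0639. A lower share of small macrophages, monocytes and dendritic cells in H_C than in L_C cannot be told apart from a change within cells: 14 markers of these types had a median log2 fold change of -0.456 against -0.871 for 13 MHC class II genes (exact rank-sum p across genes, which are not independent, of 0.00228), and only 3 of the 14 reached an average log2 CPM of 3. An effect of glucose and ox-LDL, the factors of the design, on interferon signalling may also account for it and was not tested further. The interaction also holds L_O against L_C, so a lack of mannitol in L_O cannot be told apart from these explanations there.

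The ox-LDL effect differed between glucose levels for Ccr1 by 0.649 and for Gas6 by -0.459 on the log2 scale. It also differed for the lists of LXR targets (camera adjusted p = 4.04e-05), inflammatory genes (0.00434), cell cycle (6.71e-06) and matrix remodelling (6.71e-06), none of which passed with an estimated correlation (0.066 to 0.308). The lists of L_C replicate 1 for interferon-stimulated genes (0.604, gap of 0.833 of the range), H_C replicate 4 for MHC class II (-0.396, 0.897), glucose sensing (-0.187, 0.926) and lipid droplet and PPAR genes (-0.299, 0.851), and H_O replicate 3 for alternative activation (-0.524, 0.919) lay below their groups. Those of L_C replicate 3 for LXR targets (0.19, 0.97) and L_C replicate 2 for T and NK cell markers (0.717, 0.906) and the mast cell and basophil marker (1.14, 1) lay above them. For the mast cell and basophil marker, a gene near the floor, the other L_C libraries were tied at -2.317, which fixes that gap. L_O replicate 2 had 14.8% of its counts in the 10 largest genes, against 14.6% in the other L_O libraries (0.923).

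Among the genes named in the text, given with their CPM in the outlying library and the gap as a fraction of the range, these stood apart. L_C replicate 4 lay above the other 3 in Cpt1a (127 CPM, 0.839), Gas6 (70.5 CPM, 0.933) and Prg4 (47.4 CPM, 0.945) and below them in Gadd45b (68.1 CPM, 0.837) and Rnaseh2c (3.6 CPM, 0.899). H_O replicate 2 lay above the other 3 in Acod1 (86 CPM, 0.881), Apoc2 (10.9 CPM, 0.892), Htra1 (6.73 CPM, 0.866), Iigp1 (28.2 CPM, 0.835), Nlrp3 (28.6 CPM, 0.836), Sgk1 (496 CPM, 0.86), Tgtp1 (6.83 CPM, 0.881) and Tgtp2 (22.9 CPM, 0.872). L_O replicate 1 lay above the other 3 in Gbp4 (10.3 CPM, 0.899), Gbp5 (12.2 CPM, 0.835), Gbp8 (36 CPM, 0.93), Glcci1 (9.49 CPM, 0.961), Tgtp1 (8.22 CPM, 0.928) and Tgtp2 (24.9 CPM, 0.834). L_C replicate 3 lay above the other 3 in Adam8 (366 CPM, 0.905) and Ddit3 (42.3 CPM, 0.871). L_O replicate 2 lay above the other 3 in Gadd45b (33.9 CPM, 0.83), Itgax (400 CPM, 0.911) and Slc27a6 (4.75 CPM, 0.857) and below them in Abca1 (153 CPM, 0.916). L_C replicate 2 lay above the other 3 in Clic5 (68 CPM, 0.938). H_C replicate 2 lay above the other 3 in Clec10a (8.38 CPM, 0.921) and below them in Eno1 (257 CPM, 0.893). H_C replicate 3 lay above the other 3 in Dusp6 (9.45 CPM, 0.87). L_O replicate 3 lay above the other 3 in Slc6a6 (1846 CPM, 0.869). H_O replicate 1 lay above the other 3 in Marveld1 (59 CPM, 0.869). H_O replicate 3 lay below the other 3 in Spp1 (1446 CPM, 0.884).

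Other splits of the same libraries were run for the counts of genes. In each of the 4 pairwise comparisons only the real split, 1 of 35, gave as many genes: 3490, 2962, 1728 and 826, against at most 1, 1, 1 and 0 in the other splits. The latter counts are of edgeR at the same threshold in these refits. The share of 1 in 35 is the smallest these splits allow, and it was not adjusted over the comparisons. Every other split mixes the groups, so a real difference widens its spread and leaves few calls. The labels do not say that replicates were separate cultures, so exchanging libraries cannot exclude chance between cultures. For the interaction 3 of 100 splits gave at least the 2 genes of the real split. The highest other split gave 33 after L_O replicate 1 and H_O replicate 3 were exchanged. The cause of that count was not tested, and it may be the glucose difference itself. The splits do not settle whether chance can be excluded for the interaction either, because they also exchange libraries between glucose levels that differed in many genes. The interaction count was also 0 in limma-voom, 0 with the replicate block and 0 in 12 of the 16 fits without a library, with up to 53 in the rest, against 95 in DESeq2 and 1161 genes at an unadjusted p under 0.05 in edgeR.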

How the results depend on the processing

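No scaling beyond library totals, the array quality weights and the leave-outs for the agreements were chosen only after the result was seen. The counts for ox-LDL in low and high glucose stayed within 1.5 times their values under each alternative run, as did the count for high glucose without ox-LDL except in the fit of the 8 libraries compared, which gave 914 instead of 1728. For high glucose with ox-LDL that fit gave 1619 instead of 826, array quality weights gave 1846, and leaving out a library gave 526 to 1763. Array quality weights gave L_C replicate 4 a weight of 0.0925, against 0.732 to 1.56 for the others, and the common dispersion was 0.0212 with this library and 0.0151 without it. The count of 2 for the interaction was 95 in DESeq2, 75 with array quality weights, 0 in limma-voom and 0 to 53 when a library was left out, against 1161 genes at an unadjusted p under 0.05 in edgeR. The correlation across genes of the ox-LDL effects was 0.495, and 0.695 with the stricter filter, which tests fewer genes at low counts. When a library was left out it was 0.4 to 0.469. For the glucose effects these values were 0.276, 0.434 and 0.184 to 0.277. The gene set differs too, since without L_C replicate 4 the filter passed 13734 genes, against 13527 with all libraries. The lists past the threshold, 13, 11, 8, 6 and 6 in the order ox-LDL in low and high glucose, glucose without and with ox-LDL and interaction, were 4, 7, 0, 0 and 0 with an estimated correlation, and 21, 15, 15, 11 and 4 with fry. The calls lost with fry were interferon-stimulated genes (0.0639) and inflammatory genes (0.13) in the interaction and oxidative phosphorylation (0.0806) for ox-LDL in high glucose. For ox-LDL in low and high glucose, fry added scavenger receptors (1.15e-08 and 6.54e-09) and lipid droplet and PPAR targets (0.000813 and 0.00162) as higher. It added LXR targets as lower in low glucose (0.00323) and higher in high glucose (0.00235). Scavenger receptors had median log2 fold changes of -0.113 and -0.0961, and LXR targets -0.0771 in high glucose, so these medians do not bear out fry's rises. Some counts of list members also moved by more than 1.5 times without L_C replicate 4: from 5 to 16 higher in oxidative phosphorylation and 2 to 4 in lysosome for ox-LDL in high glucose, and from 4 to 8 lower in interferon-stimulated genes and 4 to 10 in lysosome for high glucose with ox-LDL. Leaving out a library gave 5 to 11 lists for the interaction. Of the 44 calls, an estimated correlation kept 11, fry kept 41 and added 25, RLE kept 43, and upper-quartile and no scaling all 44, while fits without a library kept 40 to 44. Oxidative phosphorylation in the interaction, which did not pass, turned from lower to higher without L_C replicate 4 (adjusted p = 0.0465, with 0.0465 to 0.896 over the leave-outs). For each of these differences the cause was not tested.

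With the replicate number as a block (the replicate block), the interaction count was 0, the other counts stayed within 1.5 times, and of the 44 list calls 43 were kept, with glycolysis for ox-LDL in high glucose lost at an adjusted p of 0.0547. The values showed no pairing by number: the correlation of same-numbered deviations ran from -0.165 to 0.103, and 3 of 16 libraries matched their own number best. A shared animal or day with a small effect would not show in these values, so pairing is not excluded. What a call lost under the block means therefore cannot be told. Of the 180 gene results named as changed, 168 kept the call under each alternative run and 12 lost it under at least 1, and of 36 that did not pass 14 passed under at least 1, and none changed sign past the threshold.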

Other observations

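Of the tests in this part, that of the mannitol difference and the settings without scaling were chosen only after the result was seen. Genes of alternative activation, a state driven by interleukin 4, went both ways with ox-LDL. In low glucose 4 of 14 rose and 4 fell, the same adjusted over the list alone, with Mrc1 (log2 fold change 1.13 ± 0.047, SE, n = 4 per group) and Clec10a (1.03 ± 0.14) among those higher. In high glucose 3 rose and 4 fell (3 and 5 adjusted over the list alone; edgeR and camera, two-sided, list adjusted p = 0.741 in low and 0.901 in high glucose). With high glucose 1 rose and 3 fell without ox-LDL (2 and 4 adjusted over the list alone), Chil3 being the gene that rose (0.39 ± 0.088) and Mrc1 among those that fell (-0.33 ± 0.047). In the presence of ox-LDL 1 rose and 3 fell with high glucose, the same adjusted over the list alone, and those that fell included Mrc1 (-0.36 ± 0.047) and Clec10a (-0.67 ± 0.13). The list's adjusted p in these comparisons was 0.228 and 0.0685, the latter 0.0427 with no scaling beyond library totals. With fry the list passed in all 4 comparisons, with adjusted p of 5.93e-05 and 8.45e-05 as higher for ox-LDL and 7.89e-05 and 0.000186 as lower for high glucose. These directions are the ones fry gives. The median log2 fold change for ox-LDL was 0.0637 in low and -0.167 in high glucose, so the members' values do not bear out a rise in high glucose. Hypoxia targets passed in none of the 4 comparisons as a list of 18 (camera adjusted p = 0.92, 0.901, 0.765 and 0.87), although 4 rose and 5 fell with ox-LDL in low glucose, the same adjusted over the list alone. The chemokine receptor gene Ccr2, a monocyte marker, fell with high glucose without ox-LDL (-0.80 ± 0.22, adjusted p = 0.0201), and its adjusted p was 0.0507, 0.0508 and 0.0726 without L_C replicate 1, L_C replicate 2 and H_C replicate 1 (0.000218 to 0.0726 over the alternatives).

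Markers of further cell types did not pass as lists in the 4 pairwise comparisons. Of 5 dendritic cell markers 2 fell with ox-LDL in low glucose and 1 in high glucose, the same adjusted over the list alone (camera adjusted p = 0.0685 and 0.429, the former 0.0227 with no scaling beyond library totals, 0.0338 without L_O replicate 3, 0.039 with the replicate block and 0.0011 with fry), and the 2 were 1 without L_C replicate 4. Their score, the mean of log2 CPM less each gene's mean over all libraries, lay between 0.451 and 0.997 in L_C. In L_O it lay between -1.16 and 0.093. This separation had an exact permutation p of 0.0286, the smallest that 4 against 4 allow, and 0.0471 after adjustment over the 28 lists. The same score had a mean of 0.377 in H_C and -0.438 in H_O, with the same exact p of 0.0286 and 0.0572 after adjustment, which did not pass. The adjusted values differ only because more lists reached 0.0286 in low glucose, so they do not tell the comparisons apart for these markers. This score test was not among the tests fixed beforehand. In low glucose 4 further lists that camera did not call gave the same 0.0286 and 0.0471 by this score, with LXR targets, matrix remodelling and neutrophil markers lower and lipid droplet and PPAR targets higher. Mesothelial and fibroblast markers scored 1.54 in H_C replicate 3 and 0.902 in H_O replicate 4, against at most 0.711 in the other 14 libraries, and their interaction had a camera adjusted p of 0.0785, or 1.63e-05 without H_C replicate 3 and 0.021 without H_O replicate 3. In the 4 pairwise comparisons their list had camera adjusted p of 0.0847, 0.887, 0.933 and 0.0985, the first 0.0168 with no scaling beyond library totals, 0.0439 without L_C replicate 1 and 0.0242 without H_C replicate 3, and the last 0.0178 without H_C replicate 3 and 0.0333 without H_O replicate 3. The list results were 0.583, 0.887, 0.707 and 0.677 for 6 B cell markers, 0.761, 0.826, 0.464 and 0.531 for 6 markers of erythroid cells and platelets and 0.733, 0.949, 0.267 and 0.436 for Hdc, the only measured mast cell and basophil marker, in the same order of comparisons. With fry, B cell markers passed in the first of these (0.0127) and Hdc in the third (0.0412). Hdc was near the floor, at 0 CPM in L_C replicate 4 and a mean of 0.184 CPM in the other L_C libraries.

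Some lists that did not pass for high glucose without ox-LDL did so without L_C replicate 4. Without that library, oxidative phosphorylation genes passed as lower (camera adjusted p = 0.00821, against 0.973 with it), NRF2 genes as higher (0.0109, against 0.077) and lipid droplet and PPAR genes as lower (0.0193, against 0.232). With all libraries NRF2 genes also passed with no scaling beyond library totals (0.0462) and with fry (0.000107), and lipid droplet and PPAR genes with fry (0.00504). None of the 3 lists passed camera with an estimated correlation and all libraries, at adjusted p of 0.992, 0.112 and 0.317 in the order above. That setting was not run without L_C replicate 4. Without L_C replicate 4 the median log2 fold changes of the 3 lists were -0.10, 0.10 and -0.08, against -0.02, 0.06 and -0.03.

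Transporter genes for osmolytes were higher in high glucose, although the low glucose control medium held mannitol to balance it. For Slc5a3, Slc6a12 and Slc38a2, picked from the list of 15 NFAT5 targets after its result was seen, the lowest log2 fold change over 4 scalings and both glucose comparisons was 0.595. Over the 4 scalings the median of all genes in these comparisons lay only between -0.00454 and 0.0306. Genes already picked with a larger rise could hardly turn under them, so this test says nothing further on the scaling between libraries. The whole list had a median log2 fold change of 0.224 without ox-LDL and 0.223 with it. The lack of a named mannitol addition in L_O cannot be told apart from an effect of glucose in H_O against L_O. It would make the rise larger with ox-LDL, and the median of that difference over the 15 members was 0.0669 (camera adjusted p = 0.86), or -0.0141 without L_C replicate 4 (0.514), so its sign is open too. H_C against L_C holds no L_O library, so a lack of mannitol in L_O cannot account for the rise there. The design gives glucose as a biological explanation, which was not tested apart from osmolality, since no osmolality was available to this work, and an unequal uptake or effect of mannitol and glucose may also account for the pattern.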
